A study of Papio anubis with 34 samples.

How the data were processed

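Prefrontal cortex of 34 female olive baboons was snap-frozen at necropsy, per the labels. Total RNA was extracted from the frozen tissue, and stranded libraries were made with a kit that removes ribosomal RNA (KAPA RNA HyperPrep with RiboErase) and sequenced as paired reads on a NovaSeq, per the labels' protocols. The submitters' processing notes name bcl2fastq, STAR 2.5.3 and Partek, without saying which step each served. The genome build is not given in the sources used here. Because the file names chromosomes only by sequence accession and no build is stated, no coordinates are printed, and genes are identified by symbol and GeneID.

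The authors deposited 2 tables of 89424 transcripts by 34 libraries. One holds estimated counts per transcript, deposited as not normalized: 27.1% of its values above 0 are whole numbers within 0.001, and library totals run from 2500762 to 28495030. The other holds a normalized signal, deposited by the authors: tested on the file, it equals the estimated count times 1 constant per library. Over values of 10 or more counts this holds within a relative deviation of 9.34e-06, except for ALB in the library labelled younger replicate 8, listed as 1260000 counts, where the deviation is 0.0028. These constants lie between 0.988 and 1.04 times a TMM scaling to CPM. How it was made is not given in the sources used here. Columns were assigned to animals by title, and 0 columns belonged to no listed sample.

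Estimated counts were summed to 35741 genes by the GeneID in the file and rounded to whole numbers. The 24 rows that name no gene, mitochondrial ribosomal and transfer RNAs, were left out of library sizes and tests. They held 0.256 to 1.48% of counts (mean 0.851 ± 0.258%, SD, n = 34). Where several GeneIDs share a symbol (377 extra copies), the symbol names the copy of the highest count. Of the GeneIDs, 31305 were found in the reference table of gene names and 4436 were not. Of 1270 symbols in 43 gene lists written before the data were examined, 1189 were found by the file's symbol or by the table's current one, and 41 lists had 5 or more tested members.

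Libraries were grouped by labelled age, as a continuous number and as 3 bands of 12, 11 and 11 animals. Each animal is 1 replicate. The replicate numbers within bands follow the order of deposit and pair nothing. Genes were kept by filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with edgeR 4.0.16 (robust quasi-likelihood F test) in R 4.3.3. The slope is in log2 units per 10 years, its SE is the absolute slope divided by the square root of F, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Curvature was tested as the quadratic term of centred age, and transcript usage by diffSpliceDGE over genes with 2 or more kept transcripts, with Simes p per gene. Lists were tested with cameraPR of limma 3.58.1 on the signed square root of F with a preset correlation of 0.01, and beside it with camera at an estimated correlation and with fry. Scores per library are means of z-scored log2 CPM (prior count 2) over the list, correlated with age by Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples, adjusted over 41 lists, and r was repeated without the 2 libraries farthest from the median age.

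Alternatives were other scalings (RLE, upper quartile), DESeq2 1.42.0, limma-voom, no filter or a filter of 1 CPM in 17 libraries, robust estimation off, the title suffix R as a covariate or its 6 libraries left out, log2 library size, surrogate variables (sva 3.50.0) or 2 list scores (oligodendrocyte and excitatory neuron) as covariates, limma on the log2 of the deposited normalized signal with pseudocounts of 1 and 0.1, transcripts as the unit, the rank of age, the 2 youngest and 2 oldest animals left out, and each library left out in turn. These and the tests were fixed before the data were examined. The analysis of 33 libraries, with every alternative repeated, was added after the library labelled younger replicate 8 was seen to stand apart. Library size and surrogate variables as covariates for the lists were also added after the results were seen.

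The genes named are, by a rule fixed in advance, the 12 of smallest p per direction that pass the linear fit with the same sign between bands and a symbol, or, where fewer pass, the next up to 6 per direction, said not to pass. To these come up to 4 members of smallest p for each list described, the smallest p for curvature and transcript usage, and 16 marker genes, of which 15 were matched by symbol. The rule was repeated on the 33 libraries. Genes of the library labelled younger replicate 8 (ALB, APOB and the liver list), PCDH7 and SERPINA1 were named after their values were seen. Some genes that the rule names are not reported here.

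The steps were tested on simulated data made from the real means, library sizes and dispersions of the 33 libraries. For the slope on age over 15865 genes, 42% of 100 genes given 0.5 log2 units per 10 years and 85% of 100 given 1 were recovered, with 7 unchanged genes called. For older minus younger over 15696 genes the shares were 45% and 82%, with 4 unchanged genes called. For transcript usage 49% of 200 genes with 1 transcript given a slope of 2 were recovered over 7402 genes, with 10 unchanged genes called. A list of 32 genes given 0.3 was recovered with 0 other lists called. Means, library sizes and dispersions carry no correlation among the genes of a list. In the real 33 libraries the estimated correlation ran from -0.014 (choroid plexus and ependymal markers) to 0.91 (oligodendrocyte and myelin markers). The simulated list result therefore cannot tell how often lists of correlated genes are called wrongly. With 2500762 to 28495030 counts per library, genes of a few CPM have wide errors, and intervals on shares of a single library cover counting error only. The median SE of a gene's slope was 0.13 in the 33 libraries and 0.19 in 34.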

Results

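Total RNA from the prefrontal cortex of 34 female olive baboons (Papio anubis) was sequenced, 1 library per animal, to ask how the cortical transcriptome differs with age in animals kept on a standard diet. The animals were 7.45 to 22.12 years old, with a median of 14.3 years (mean 14.8 ± 4.34 years, SD, n = 34), and age was the only variable that the labels give. For comparisons between ends of the range the animals were ordered by age into a younger band (7.45 to 12.02 years, n = 12), a middle band (12.86 to 18.26 years, n = 11) and an older band (18.42 to 22.12 years, n = 11). The libraries were stranded and depleted of ribosomal RNA. They held 2500762 to 28495030 estimated counts, with a median of 6243534, and 12892 to 19344 genes had 10 or more counts in a library. Mean totals were 7849399 ± 6129711 in the younger band (SD, n = 12), 6654111 ± 3258332 in the middle band (SD, n = 11) and 10008395 ± 7124832 in the older band (SD, n = 11). The correlation of log2 library size with age did not pass over the 33 libraries used below (Pearson's r = 0.21, permutation p = 0.241; Spearman's rho = 0.20, permutation p = 0.265; n = 33). The titles of 6 libraries carry a suffix R that the labels do not explain. Of these, 3 belong to the younger band and 3 to the older band. The libraries with the suffix held 10551785 (older replicate 1) to 28495030 estimated counts (older replicate 3). Of the libraries without it only older replicate 2 (11948573) and middle replicate 1 (14446285) reached that range, so suffix and library size largely coincided.

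The library labelled younger replicate 8, from an animal of 10.99 years, did not carry the transcripts of cortex that the other 33 libraries carried. ALB, which encodes the plasma protein albumin, took 5.89% of its gene counts (95% Clopper-Pearson interval 5.88 to 5.90%), against at most 0.00192% in the other 33 libraries. APOB, the apolipoprotein of low-density lipoprotein, took 2.78% (interval 2.77 to 2.79%), against at most 0.000942% elsewhere. SNAP25, a presynaptic membrane fusion protein of neurons, stood at 7.39 CPM, the usual scaling of counts to a common library total, against 1837 to 3069 CPM in the other libraries, and MBP, the myelin basic protein, at 17.6 CPM. Of 17 measured genes typical of liver, 17 were above every other library. Of 16 genes typical of cortex, 16 were below every other library. The median Pearson correlation of its log2 CPM with the other libraries was 0.44 over the 16232 genes tested on age, whereas no other library had a median below 0.93. Over all 35741 genes, with 1 added to the CPM before taking log2, it was 0.703, and no other library had a median below 0.978. The intervals on shares cover counting error only. The ALB count is listed as 1260000, which is 0.28% below the count that the deposited normalized signal gives, and with that count its share would be 5.91%. The library was kept in the fits to all 34 libraries, as fixed before the data were examined, and each comparison below is given also for the other 33 libraries, a choice made after these values were seen. Band means below are over those 33 libraries (n = 11 in each band) and carry the TMM scaling, whereas CPM values of the library labelled younger replicate 8 do not.

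**Figure D1:**
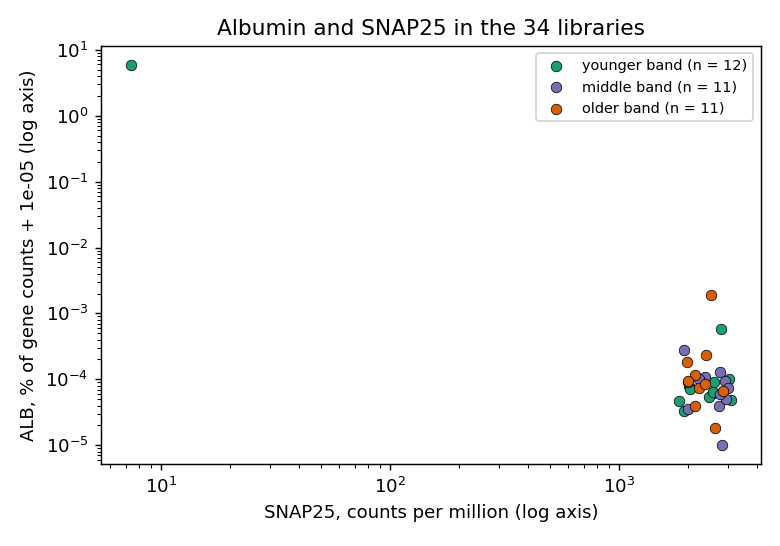
Each point is 1 of the 34 libraries, coloured by age band, with SNAP25 in CPM on a log x axis and ALB as a percent of gene counts (plus 1e-05) on a log y axis. The library labelled younger replicate 8 sits apart at 7.39 CPM of SNAP25 and 5.89% ALB, and the other 33 lie between 1837 and 3069 CPM with at most 0.00192% ALB.

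No gene passed an adjusted p of 0.05 for a straight-line change with age, in either set of libraries. In the 33 libraries the genes with the smallest p included HOMER1, a scaffold protein of excitatory synapses, with a slope of -0.40 ± 0.09 log2 units per 10 years (SE; GeneID 101024434). Its band means were 314 ± 57.1 CPM in the younger, 264 ± 42.8 in the middle and 236 ± 35.0 CPM in the older band (SD, n = 11 each). FRZB, a secreted antagonist of Wnt signalling, had a slope of -0.81 ± 0.18 (25.4 ± 13.1 CPM in the younger and 13.8 ± 3.41 CPM in the older band; GeneID 101010410). The adhesion receptor gene ADGRG6 had a slope of -0.71 ± 0.16 (27.4 ± 9.71 and 15.8 ± 3.07 CPM; GeneID 101019728). F5, coagulation factor V, had the smallest p of all (slope -2.34 ± 0.51, p = 5.1e-05) at a low level, 2.85 ± 3.58 CPM in the younger and 0.448 ± 0.246 CPM in the older band. LDLRAD4, an inhibitor of transforming growth factor beta signalling, had a slope of -0.34 ± 0.09 and the small GTPase-like gene RERGL one of -0.79 ± 0.20. On the positive side, SFRP1, another secreted Wnt antagonist, had a slope of 1.11 ± 0.28 (65.5 ± 31.2 CPM in the younger and 149 ± 108 CPM in the older band). CERCAM had a slope of 0.77 ± 0.19 (5.28 ± 2.44 and 9.58 ± 2.18 CPM). WDR6 had a slope of 0.27 ± 0.07 (52.7 ± 5.07 and 66.5 ± 6.33 CPM). PIK3IP1, an inhibitor of phosphatidylinositol 3-kinase, had a slope of 0.35 ± 0.09 and the metalloprotease gene ADAMTS14 one of 1.45 ± 0.39. None of the genes named here passed, with adjusted p between 0.373 and 0.509. Several of these slopes were more than 1.5 times smaller with added covariates. With the oligodendrocyte and excitatory neuron scores as covariates they were 0.51 ± 0.17 for SFRP1, 0.86 for ADAMTS14 and -0.49 for FRZB. With surrogate variables they were 0.58 ± 0.16 for SFRP1, 0.88 for ADAMTS14, -0.45 for FRZB, -1.24 for F5, -0.44 for ADGRG6, -0.51 for RERGL and -0.23 for LDLRAD4. The slope of SFRP1 was 1.41 ± 0.30 without the R libraries and 0.78 ± 0.34 in all 34 libraries.

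The test was edgeR's quasi-likelihood F test with Benjamini-Hochberg adjustment. In the 33 libraries 0 of 16017 genes passed in either direction, with 608 genes of positive and 594 of negative slope at an unadjusted p under 0.05. DESeq2 and limma-voom also gave 0 in both directions. In all 34 libraries 0 of 16232 genes passed, with 387 genes of positive and 1167 of negative slope at an unadjusted p under 0.05 and a smallest adjusted p of 0.0778. There DESeq2 called 6 genes higher and 213 lower, and limma-voom 0 in both directions. By p the negative side in 34 libraries was headed by F5, TTR, ITIH4, IQGAP2, CFI and BAAT, genes with high expression in liver. Their slopes ran from -10.26 for TTR to -6.22 for IQGAP2, and they held 746 to 4350 CPM (F5 and ITIH4) in the library labelled younger replicate 8. Without that library all 6 slopes were smaller: -2.34 ± 0.51 for F5, -1.67 ± 0.65 for TTR (p = 0.0152), -0.87 ± 0.30 for IQGAP2 (p = 0.00631), -0.59 ± 0.35 for ITIH4 (p = 0.104), -0.45 ± 0.26 for CFI (p = 0.0929) and -0.07 ± 0.25 for BAAT (p = 0.781). The genes of smallest p on the positive side included PIK3IP1, WDR6, CERCAM, MCAM (slope 0.78 ± 0.22) and ACTA1 (slope 0.91 ± 0.26). The slope of MCAM was 0.22 ± 0.14 (p = 0.115) with list score covariates and 0.26 ± 0.14 (p = 0.0765) with surrogate variables, and 0.22 and 0.27 with these in the 33 libraries against 0.75 ± 0.22 without. On counts simulated for the 33 libraries, the test recovered 42% of 100 genes given a slope of 0.5 log2 units per 10 years and 85% of 100 given a slope of 1, over 15865 genes. Small slopes of single genes were often not detectable at this number of animals and depth.

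**Figure D2:**
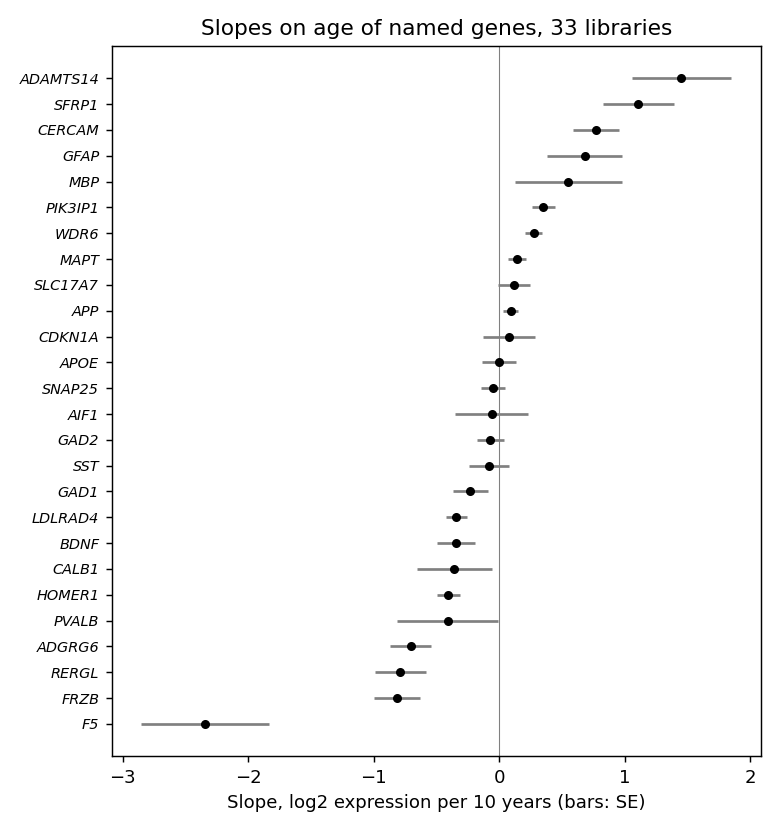
The x axis gives the slope on age in log2 expression per 10 years from edgeR over 33 libraries, with bars of 1 SE, for genes named by rule and marker genes on the y axis. SFRP1 stands at 1.11 and FRZB at -0.81, and none of the genes shown passed an adjusted p of 0.05.

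Genes of oligodendrocytes and myelin, the cells and sheath that insulate axons, were higher with age as a list (24 genes, median slope 0.76 log2 units per 10 years; camera adjusted p = 3.03e-12 over 41 lists). That p rests on a preset correlation of 0.01 among the genes of a list, as does every list call below. The correlation estimated for this list was 0.91. With the estimated correlation the call was lost (camera p = 0.0469, adjusted p = 0.526). Of the 24 genes, 12 had a positive and 0 a negative slope at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone or over all genes. SOX10, a transcription factor of the oligodendrocyte lineage, had a slope of 0.86 ± 0.30, with 27.8 ± 17.6 CPM in the younger and 56.02 ± 34.1 CPM in the older band (SD, n = 11 each). MYRF, a regulator of myelin genes, had a slope of 1.02 ± 0.40 (52.0 ± 45.9 and 118 ± 82.5 CPM), and MAL and CARNS1 had slopes of 0.96 ± 0.39 and 0.99 ± 0.41. The mean score of the list per library correlated with age at r = 0.39 (permutation p = 0.0241, adjusted p = 0.403 over 41 lists; rho = 0.39, permutation p = 0.0237, adjusted p = 0.354; n = 33). The value of r was 0.32 without the 2 libraries farthest from the median age and 0.32 (permutation p = 0.0777) without older replicate 6, of 22.12 years. In the 28 libraries without the suffix R, r was 0.51 (permutation p = 0.00493, adjusted p = 0.101 over 41 lists). There rho was 0.50 (permutation p = 0.00758, adjusted p = 0.104), so neither passed. The 5 libraries with the suffix, fewer than the 6 set as the least for a correlation, had scores of 1.68 at 9.42 years, -0.12 at 11.95, 1.05 at 18.48, -0.44 at 18.61 and -0.01 at 19.81 years, so the youngest of them had the highest score. In all 34 libraries the list was likewise called (median slope 0.82, adjusted p = 7.27e-11), and the call was lost there too with an estimated correlation (p = 0.0255, adjusted p = 0.523). The correlation of the score with age did not pass there (r = 0.41, permutation p = 0.0148, adjusted p = 0.607; rho = 0.41, permutation p = 0.0153). With surrogate variables as covariates the median slope of the list was 0.14 in the 33 libraries (adjusted p = 0.0177), and 0.13 in all 34, where the call ended as the slopes shrank (p = 0.00836, adjusted p = 0.0599). The spread within each band was large, with MBP at 2601 ± 2553 CPM in the younger and 4281 ± 3052 CPM in the older band.

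Genes of the postsynaptic density, the protein scaffold under excitatory synapses, were lower with age as a list in the 33 libraries (27 genes, median slope -0.13; adjusted p = 2.84e-07), a call lost with an estimated correlation (p = 0.0615, adjusted p = 0.526). Of the 27 genes, 5 had a negative and 0 a positive slope at an unadjusted p under 0.05, and HOMER1 was the 1 gene that passed when adjusted over the list alone. SHANK2 had a slope of -0.29 ± 0.10 (176 ± 42.5 CPM in the younger and 146 ± 25.6 CPM in the older band), DLGAP2 one of -0.23 ± 0.09 and DLGAP3 one of -0.30 ± 0.12, all 3 of them scaffold proteins. The list score correlated with age at r = -0.36 (permutation p = 0.0413, adjusted p = 0.403; rho = -0.37, permutation p = 0.0326, adjusted p = 0.354; n = 33). The relation rested in part on the 2 libraries farthest from the median age, without which r was -0.17. In the 28 libraries without the suffix R the score correlated with age at r = -0.60 (permutation p = 0.00068, adjusted p = 0.0279 over 41 lists; rho = -0.57, permutation p = 0.00152, adjusted p = 0.0623). Without the 2 farthest r was -0.57 there, and this was the 1 list whose r passed. Leaving out only the suffix R library younger replicate 4, of 9.42 years, moved r to -0.50 (n = 32), and leaving out younger replicate 7, of 7.45 years, moved it to -0.27 (permutation p = 0.14). In the 5 libraries with the suffix the scores were -1.36 at 9.42 years, 0.09 at 11.95, 0.75 at 18.48, 0.48 at 18.61 and -0.15 at 19.81 years, so the youngest of them had the lowest score. In all 34 libraries this list was not called without covariates. It was called lower there with the list score covariates, the myelin and excitatory neuron scores (median slope -0.10, adjusted p = 0.000265). It was also called lower there with surrogate variables (median slope -0.06, adjusted p = 0.000602). These settings gave medians in the 33 libraries of -0.04 (adjusted p = 0.00283) and -0.07 (adjusted p = 4.26e-08). The score fell as the oligodendrocyte and myelin score rose (r = -0.59, permutation p = 0.00022; rho = -0.46, permutation p = 0.00815; n = 33), with r = -0.47 without the 2 libraries farthest from the median myelin score.

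**Figure D3:**
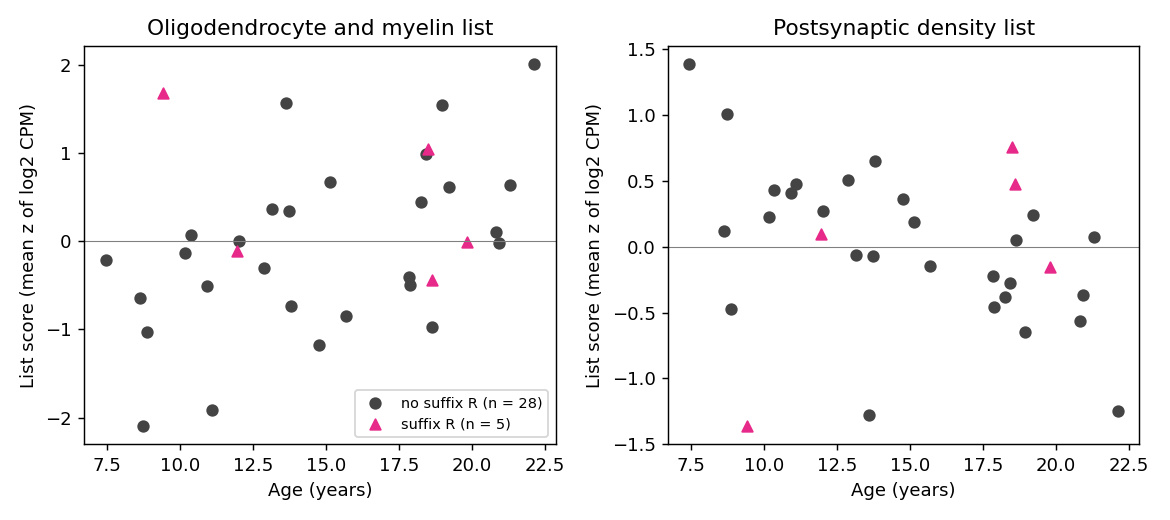
Each point is 1 of 33 libraries, with age in years on the x axis and the mean z-score of log2 CPM over the list on the y axis; triangles are the 5 libraries with the title suffix R. The oligodendrocyte and myelin score correlates with age at r = 0.39 and the postsynaptic density score at r = -0.36, and neither passes adjustment over 41 lists.

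Of the 13 genes encoded by mitochondrial DNA, which form part of the respiratory chain, 4 had a negative slope at an unadjusted p under 0.05 and 4 passed when adjusted over the list alone, with 0 of them passing over all genes. The list was lower with age (median slope -0.24; adjusted p = 0.000105), a call lost with an estimated correlation (p = 0.0576, adjusted p = 0.526). With list score covariates it was called with a median slope of -0.11 (adjusted p = 0.0106). The list score correlated with age at r = -0.36 (permutation p = 0.0423, adjusted p = 0.403 over 41 lists; rho = -0.37, permutation p = 0.0345, adjusted p = 0.354; n = 33). The value of r was -0.27 without the 2 libraries farthest from the median age and -0.31 (permutation p = 0.0849) without older replicate 6. In the 28 libraries without the suffix R it was -0.40 (permutation p = 0.0353, adjusted p = 0.182). There rho was -0.42 (permutation p = 0.0257, adjusted p = 0.15). The score fell as the oligodendrocyte and myelin score rose (r = -0.38, permutation p = 0.03, adjusted p = 0.0631 over 40 lists; rho = -0.37, permutation p = 0.0342; n = 33), with r = -0.27 without the 2 libraries farthest from the median myelin score. ND4L had 1818 ± 201 CPM in the younger and 1374 ± 286 CPM in the older band (slope -0.36 ± 0.10), ND3 a slope of -0.29 ± 0.09, COX3 one of -0.32 ± 0.10 and ATP8 one of -0.27 ± 0.10. ND4L and ATP8 overlap their neighbours ND4 and ATP6 on the mitochondrial genome, so the split of counts among them is uncertain. The nuclear-encoded genes of oxidative phosphorylation were lower as a list with a small median slope of -0.07 (51 genes, adjusted p = 0.000278; estimated-correlation p = 0.236). In it 3 genes had a negative slope at an unadjusted p under 0.05, NDUFB1, NDUFA12 and ATP5C1, and 0 passing. The 73 cytosolic ribosomal protein genes had a median slope of -0.06 (adjusted p = 0.00276; estimated-correlation p = 0.32), with 5 negative and 2 positive slopes at an unadjusted p under 0.05. Many of these have near-identical pseudogenes, so their counts are uncertain.

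Calcium buffering and signalling genes were lower as a list (31 genes, median slope -0.11; adjusted p = 0.000192; estimated-correlation p = 0.0747, adjusted p = 0.526). Their score correlated with age at r = -0.34 (permutation p = 0.0497, adjusted p = 0.403; rho = -0.42, permutation p = 0.015, adjusted p = 0.354; n = 33), with r = -0.16 without the 2 libraries farthest from the median age and -0.23 (permutation p = 0.197) without older replicate 6. In the 28 libraries without the suffix R the calcium score had r = -0.45 with age (permutation p = 0.0137, adjusted p = 0.141). There rho was -0.52 (permutation p = 0.00502, adjusted p = 0.103). CAMK4, a calcium-dependent kinase of neurons, had 80.04 ± 15.6 CPM in the younger and 59.1 ± 7.89 CPM in the older band (slope -0.39 ± 0.11) and was the 1 gene passing when adjusted over the list alone. ATP2B1, a plasma membrane calcium pump, had a slope of -0.16 ± 0.06 and CAMKK2 one of -0.22 ± 0.09. Some other neuronal lists were also called lower. These were GABA synthesis, transport and receptors (25 genes, median slope -0.07, adjusted p = 0.01; estimated-correlation p = 0.133), inhibitory neuron markers (25 genes, median slope -0.16, adjusted p = 0.0131; estimated-correlation p = 0.21). They were also glutamate receptors and transport (29 genes, median slope -0.11, adjusted p = 0.0419; estimated-correlation p = 0.265) and immediate early genes (25 genes, median slope -0.09, adjusted p = 0.0181; estimated-correlation p = 0.53). Among the immediate early genes, which neurons switch on within minutes of activity, HOMER1 and EGR3 (slope -0.46 ± 0.13; 100.1 ± 31.7 and 73.0 ± 14.2 CPM) were the 2 that passed when adjusted over the list alone. The immediate early score had r = -0.11 with age (permutation p = 0.551) and rho = 0.001 (permutation p = 0.995, n = 33). Its mean was 0.03 in the younger and 0.04 in the older band. Among the inhibitory neuron markers CRH, the gene of a stress neuropeptide, had a slope of -0.65 ± 0.23. The glutamate list included the astrocyte transporters SLC1A2 (slope -0.27 ± 0.10) and SLC1A3 (slope -0.30 ± 0.11) and the receptor gene GRIN2B (slope -0.24 ± 0.09). None of these 4 lists had a gene passing over all genes. The scores of most of these lists fell as the oligodendrocyte and myelin score rose (n = 33): r was -0.76 for the GABA list (rho = -0.66), -0.74 for the calcium list (rho = -0.66), -0.67 for the inhibitory neuron markers (rho = -0.56) and -0.64 for the glutamate list (rho = -0.61). Each had an adjusted permutation p of at most 0.00332 over 40 lists, and r was -0.56 to -0.75 without the 2 libraries farthest from the median myelin score. For the immediate early genes r was -0.18 (permutation p = 0.308; rho = -0.03, permutation p = 0.889). With list score covariates none of these 5 lists was called in the 33 libraries (adjusted p = 0.323 to 0.956, median slopes from -0.04 to 0.02). These covariates are the myelin and excitatory neuron scores, so the loss cannot be assigned to the myelin score alone. Without covariates camera did not call the pan-neuronal markers there (median slope 0.02, adjusted p = 0.694). It did not call the synaptic vesicle release list (-0.01, adjusted p = 0.868) or the excitatory neuron markers (-0.15, adjusted p = 0.301). Nor did it call the list of acetylcholine, dopamine, serotonin and noradrenaline receptors (-0.09, adjusted p = 0.128).

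Markers of meningeal and perivascular fibroblasts, cells of the brain's covering and vessel walls, were lower with age as a list (14 genes, median slope -0.70; adjusted p = 5.58e-09), a call lost with an estimated correlation (p = 0.147, adjusted p = 0.712). Of the 14 genes, 7 passed when adjusted over the list alone and 0 over all genes. The collagen gene COL1A1 had 9.64 ± 13.5 CPM in the younger and 2.35 ± 2.06 CPM in the older band (slope -1.78 ± 0.58). COL3A1 had a slope of -1.55 ± 0.51, COL1A2 one of -1.76 ± 0.60 and LUM, the proteoglycan lumican, one of -1.29 ± 0.44. The list score correlated with age at r = -0.27 (permutation p = 0.128; rho = -0.18, permutation p = 0.319; n = 33). The value was r = -0.26 without the 2 libraries farthest from the median age and r = -0.33 in the 28 libraries without the suffix R (permutation p = 0.0829; rho = -0.23, permutation p = 0.236). It was highest in 2 libraries, younger replicate 10 (2.25) and younger replicate 2 (2.17), against at most 1.27 in the others, and without these 2 the correlation was r = -0.01 (permutation p = 0.959). The fibroblast score fell as the oligodendrocyte and myelin score rose (r = -0.57, permutation p = 0.00045, adjusted p = 0.00184 over 40 lists; rho = -0.39, permutation p = 0.0275, adjusted p = 0.0689; n = 33), with r = -0.43 without the 2 libraries farthest from the median myelin score. With list score covariates the list was not called in the 33 libraries (median slope 0.04, adjusted p = 0.932), nor with surrogate variables (0.15, adjusted p = 0.366). The extracellular matrix list, which shares these collagens, had a median slope of -0.10 (44 genes, adjusted p = 0.000278; estimated-correlation p = 0.278), and the endothelial list one of -0.19 (18 genes, adjusted p = 0.00385; estimated-correlation p = 0.269). Younger replicate 2 had the highest score on both (1.28 and 2.16), followed by younger replicate 10 (1.06) on the matrix list and younger replicate 9 (1.15) on the endothelial list. Neither score had a correlation with age that passed (matrix: r = -0.20, permutation p = 0.279; rho = -0.01, permutation p = 0.939; endothelial: r = -0.21, permutation p = 0.252; rho = -0.09, permutation p = 0.634; n = 33), and neither list was called in the 33 libraries with list score covariates (adjusted p = 0.409 and 0.385).

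The lysosome and autophagy list was the other list called higher in the 33 libraries, with a small median slope of 0.05 (37 genes, adjusted p = 0.0131), and was lost with an estimated correlation (p = 0.166, adjusted p = 0.712). SQSTM1, an autophagy receptor, had a slope of 0.23 ± 0.08, PSAP, the precursor of the saposins, one of 0.16 ± 0.07. NPC1, a lysosomal cholesterol transporter, had a slope of 0.48 ± 0.21 and GAA, the lysosomal glucosidase, one of 0.19 ± 0.09. In this list 0 genes passed when adjusted over the list alone. The score rose with the oligodendrocyte and myelin score (r = 0.63, permutation p = 9e-05, adjusted p = 0.0006 over 40 lists; rho = 0.61, permutation p = 0.00022, adjusted p = 0.0018; n = 33), with r = 0.56 without the 2 libraries farthest from the median myelin score. With list score covariates the call ended, at a median slope of -0.01 (adjusted p = 0.932), as it did with surrogate variables (0.02, adjusted p = 0.493). In the 33 libraries camera called 2 lists higher and 12 lower, and in 34 libraries 1 higher and 15 lower. The oligodendrocyte list and 7 lower lists were called in both sets. The complement list (median slope -0.55, adjusted p = 6.6e-12), the interferon response list (-0.55, adjusted p = 9.95e-08) and the cytokine list (-0.50, adjusted p = 0.00031) were called lower in 34 libraries. They had adjusted p of 0.355, 0.429 and 0.968 without the library labelled younger replicate 8. None of the 41 lists passed with an estimated correlation, with fry (directional or mixed) or as a score correlated with age, in either set.

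Marker genes named in advance showed no passing difference with age. In the 33 libraries GFAP, the intermediate filament of astrocytes, had 718 ± 390 CPM in the younger and 1242 ± 680 CPM in the older band (SD, n = 11 each). Its slope was 0.68 ± 0.30, with an unadjusted p of 0.0306 (adjusted p = 0.619), and 0.21 (p = 0.386) with list score covariates. BDNF, a neurotrophin, had 22.8 ± 7.89 and 18.8 ± 3.23 CPM (slope -0.35 ± 0.15, unadjusted p = 0.0267). MAPT, which encodes tau, had 539 ± 68.04 and 611 ± 80.8 CPM (slope 0.14 ± 0.07, unadjusted p = 0.0537). Slopes were 0.12 ± 0.12 for SLC17A7, the vesicular glutamate transporter, -0.23 ± 0.14 and -0.07 ± 0.11 for the GABA-synthesising enzymes GAD1 and GAD2. They were -0.08 ± 0.16 for SST, -0.36 ± 0.30 for CALB1 and -0.41 ± 0.40 for PVALB, markers of inhibitory neuron classes. SNAP25 had a slope of -0.05 ± 0.10, MBP one of 0.55 ± 0.43, the microglial gene AIF1 one of -0.06 ± 0.29, the cell cycle inhibitor CDKN1A one of 0.08 ± 0.21 and APP, the amyloid precursor, one of 0.09 ± 0.06. APOE had a slope of -0.00 ± 0.13 in the 33 libraries and -1.14 ± 0.47 in all 34, where the library labelled younger replicate 8 held 3011 CPM and the other younger libraries 290 ± 74.8 CPM (SD, n = 11). C1QB was not analysed here.

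Between the older and younger bands of all 34 libraries, 1 gene was higher and 119 were lower among 15995 tested (edgeR's quasi-likelihood F test, adjusted p under 0.05). Of the 119 lower genes, 118 had their highest level in the library labelled younger replicate 8, and they included APOB (log2 difference -9.66 ± 1.91, SE), TTR and SERPINA1, which are among the liver genes listed. The other was FRZB (-0.87 ± 0.20, adjusted p = 0.0328), and the 1 higher gene was WDR6 (0.36 ± 0.07, adjusted p = 0.0273). Without that library 0 of 15747 genes passed in either direction, with 726 higher and 806 lower at an unadjusted p under 0.05. There WDR6 had a difference of 0.33 ± 0.07 (adjusted p = 0.177) and FRZB one of -0.86 ± 0.21 (adjusted p = 0.295). DESeq2 called 1 gene higher, WDR6 (0.33, adjusted p = 0.0145), and 3 lower, F5 (-2.69), PCDH7 (-0.29) and ADGRG6 (-0.80), in the 33 libraries, and limma-voom called 0.

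No gene passed for curvature in age in either set (33 libraries: 0 of 16934 genes by edgeR, 890 at an unadjusted p under 0.05, and 0 by limma-voom; 34 libraries: 0 of 17195, 316 at an unadjusted p under 0.05). The smallest p in the 33 libraries were those of TNIP3, IL1RN and BDKRB2, none passing (adjusted p = 0.702 to 0.753). Transcript usage, the share of each gene's counts held by each of its transcripts, changed with age in 2 of 7596 genes in all 34 libraries, DST and CTNND1 (Simes adjusted p = 2.62e-06 and 0.00239). These encode a cytoskeletal linker and a protein of cell junctions. Without the library labelled younger replicate 8, 0 of 7402 genes passed, with 155 at an unadjusted p under 0.05. The smallest p were those of NSMF, ZFYVE27 and SCML1 (adjusted p = 0.694 for each). With the suffix R as a covariate 3 genes passed there, NSMF and TBC1D25 (adjusted p = 0.00344 for both) and ANKS1B (adjusted p = 0.0119), and in all 34 libraries TBC1D25 alone did (adjusted p = 0.0016), in place of DST and CTNND1. The counts are the authors' estimates per transcript, so shares among similar transcripts are uncertain.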

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

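The results over 33 libraries were added after the data were seen, as were leaving out each of those libraries for the lists, the correlation given library size, and library size and surrogate variables as covariates for the lists; the other alternatives were fixed before the data were examined. The cause of a difference was not tested unless given. In all 34 libraries, genes higher with age numbered 0, but 6 with DESeq2 and 65 without a filter, and genes lower with age numbered 0, but 213 with DESeq2, 862 without a filter and 1, LOC101012114, with list score covariates. Against 1 gene higher in the older band there were 28 without a filter, 5 with the stricter filter and 0 with limma-voom, and against 119 lower there were 723 without a filter, 3 with DESeq2 and 0 with limma-voom. Both directions gave 0 with the suffix R covariate, without the R libraries, with the log2 library size covariate, surrogate variables or list score covariates, with limma on normalized values plus 1 or plus 0.1, and with transcripts as the unit. Leaving out the R libraries also removes the library labelled younger replicate 8. Transcript usage changed in 2 genes, DST and CTNND1. With the suffix R covariate it changed in 1, TBC1D25, which is neither of them, and the F test per gene called 3, DST, GPAM (adjusted p = 0.00632) and LPIN2. The lists called, 1 higher and 15 lower, became 0 and 0 with an estimated correlation or fry, 0 and 9 with list score covariates and 0 and 5 with surrogate variables. Of the 9, 4 were among the 15, and of the 5, 3 were. Without the R libraries 3 lists were called higher and 14 lower, of which 1 and 6 were among the lists called with all 34. With the log2 library size covariate 2 were called higher and 14 lower, of which 1 and 13 were. The oligodendrocyte score is 1 of the list score covariates, so the loss of that list there is fixed by the setting and says nothing of it. In the 33 libraries, 27 genes were higher and 21 lower with age without a filter, 1 was higher and 3 lower in the older band with DESeq2, and transcript usage changed in 3 genes with the suffix R covariate, among them NSMF and TBC1D25, against 0 for each. The lists called, 2 higher and 12 lower, became 0 and 0 with an estimated correlation or fry, 0 and 5 with list score covariates (4 of the 5 among the 12) and 1 and 6 with surrogate variables (1 and 5 of them among those lists). Without the R libraries 1 list score correlated with age in either set, against 0.

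Leaving out each library in turn gave 0 genes in every case in the 33 libraries, 1 to 4 lists higher (4 without older replicate 1 or younger replicate 4, 1 without older replicate 6 or younger replicate 9) and 8 to 15 lists lower. In all 34 libraries it gave 0 to 1 genes higher with age (1 without younger replicate 7) and 0 to 55 lower (55 without younger replicate 7, 17 without younger replicate 5). Between the bands it gave 0 to 48 genes higher (48 without younger replicate 4, 8 without younger replicate 1 or 6) and 0 to 214 lower. The lower count was 0 without younger replicate 8 or any 1 of the 11 older libraries, 214 without younger replicate 4, 188 without younger replicate 6, 186 without younger replicate 7, 181 without younger replicate 11 and 180 without younger replicate 12. Of 202 slopes of 34 named genes under the alternatives, 180 had the same sign in all 34 libraries and 189 in the 33, and 22 and 13 had the other sign. Of these, 3 and 2 had an unadjusted p under 0.05 with or without the alternative. With list score covariates the slopes of BAAT (0.14), GFAP (-0.0118) and MBP (-0.31) turned in all 34 libraries and that of MBP (-0.30) in the 33, where GAD2 (0.13) turned with surrogate variables. The others that turned had p of 0.05 or more in both. MBP belongs to 1 of the lists used as a covariate. For slopes on age no named gene passed in the 33 libraries under the alternatives run for them, with a smallest adjusted p of 0.0805 without the R libraries. The median SE of a slope, 0.13, limits which genes of small slope can be seen at this depth and number of animals.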

Other observations

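Among lists that camera did not call in the 33 libraries, single genes had small unadjusted p without passing over all genes. In the complement list (adjusted p = 0.355) C7, a component of the membrane attack complex, had a slope of -2.62 ± 0.74 log2 units per 10 years, with 12.8 ± 28.3 CPM in the younger and 2.14 ± 2.71 CPM in the older band (SD, n = 11 each), and was the 1 gene passing when adjusted over the list alone. It stood at 96.2 CPM in younger replicate 2, 1 of the 2 libraries highest in the fibroblast score, against at most 18.9 CPM in the others. Without that library its slope was -0.92 ± 0.73 (p = 0.218). C7 followed the fibroblast score (r = 0.86; rho = 0.76; permutation p = 1e-05 for both, the smallest that the permutations can give; n = 33), with r = 0.81 without the 2 libraries of highest score. In the antioxidant list (adjusted p = 0.477) GSTM3, a glutathione transferase, had a slope of -0.50 ± 0.15 and GCLC, an enzyme of glutathione synthesis, one of 0.40 ± 0.13. The microglia list (adjusted p = 0.0538) included C3, the central complement component, with 87.9 ± 39.7 CPM in the younger and 164 ± 102 CPM in the older band (slope 0.74 ± 0.29, unadjusted p = 0.0144). The astrocyte list (adjusted p = 0.136) held members of both signs, with GFAP at 0.68 ± 0.30 and the transporters SLC1A2, SLC1A3 and SLC4A4 at -0.27, -0.30 and -0.24. In the list of dementia-associated genes (adjusted p = 0.177) BIN1 had a slope of 0.36 ± 0.12. Of these lists, 3 had scores that rose with the oligodendrocyte and myelin score (n = 33, p adjusted over 40 lists). These were the dementia-associated list (r = 0.60, adjusted permutation p = 0.00109; rho = 0.57, adjusted p = 0.00332), the microglia list (r = 0.49, adjusted p = 0.0122; rho = 0.40, adjusted p = 0.0611) and the antioxidant list (r = 0.49, adjusted p = 0.0127; rho = 0.58, adjusted p = 0.0028). Without the 2 libraries farthest from the median myelin score r was 0.60, 0.51 and 0.47.

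The first principal component of the 33 libraries held 15.3% of the variance and followed the oligodendrocyte and myelin score (r = 0.94; rho = 0.95; permutation p = 1e-05 for both, the smallest that the permutations can give; n = 33). Both come from the same log2 CPM, and the list members MBP, MYRF and CARNS1 were among the genes at the component's high end. The sign of the component was also set by this score, so the relation is not an independent test. The component correlated with age at r = 0.38 (permutation p = 0.0269). Its rho with age was 0.44 (permutation p = 0.0114). Along the first component the fibroblast score fell (r = -0.56) and the GABA list score fell (r = -0.81), whereas the pan-neuronal score did not (r = 0.07). Genes at its low end included the collagen genes COL1A1 and COL1A2. What drives this component was not tested. The second component held 9.60% and the third 8.004% of the variance.

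The slope of C7 without 1 library was computed after the results were seen. In the paragraphs that follow, the tests on the library labelled younger replicate 8, the test of white matter on the myelin list, the tests without the suffix R and the lists with surrogate variables were chosen after the results were seen, while those of library size, of white matter on the postsynaptic list and of other splits were written before theirs. The library labelled younger replicate 8 may hold liver RNA under a cortex label. From marker lists of 7 tissues, written before the test, the liver list had a median log2 ratio of 11.6 to the median of the other 33 libraries, with FGB at 10388 CPM and SERPINA1 at 8472 CPM beside ALB, against 0.60 for spleen and lymphoid, 0.38 for adipose, 0 for kidney, -0.35 for heart muscle and -0.49 for skeletal muscle. A mixture of liver RNA into a cortex library is argued against by the cortex markers, whose median level was 0.0389% of that in the other libraries. A swap within these 34 libraries is argued against, since 0 other libraries had albumin above 1% of counts. A single wrong label, or an exchange with a sample outside these libraries, stays open, and no biological explanation was tested.

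The rise of the oligodendrocyte and myelin list with age could reflect the amount of white matter in the sampled piece, which would lower the markers of all neurons. With age removed, the myelin score had a partial r of 0.0721 with the pan-neuronal score (permutation p = 0.689; n = 33), -0.29 with the excitatory (permutation p = 0.104), -0.14 with the synaptic vesicle (permutation p = 0.449) and -0.65 with the inhibitory neuron score (permutation p = 9e-05). Of these 4 relations 1 had a p under 0.05, so white matter and age cannot be told apart as the cause, since pan-neuronal markers with a high level in cortex could hide a small share. The suffix R as the whole cause is argued against by r = 0.51 (permutation p = 0.00493) in the 28 libraries without it, and library size by a partial r of 0.37 (permutation p = 0.0316, n = 33). With surrogate variables the median slope was 0.14 in place of 0.76 in the 33 libraries (adjusted p = 0.0177), and in all 34 the call was lost (0.13, adjusted p = 0.0599). A difference in myelin with age itself stays open, untested beside the sampling of white matter.

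The fall of the postsynaptic density list with age is a hypothesis that rests on small slopes. Given the myelin score, its partial r with age was -0.17 (permutation p = 0.347, n = 33), which lies between the bounds set for and against white matter, so that a share of white matter and age cannot be told apart as its cause. Camera still called the list lower with the list score covariates, which are the myelin and excitatory neuron scores. Its adjusted p was 0.00283 in the 33 libraries and 0.000265 in all 34, but at a preset correlation. The median slope was -0.04 in place of -0.13 in the 33 libraries. Given library size the partial r was -0.33 (permutation p = 0.0568), just short of the bound set, so library size also cannot be excluded by this test. The suffix R as the whole cause is argued against by r = -0.60 (permutation p = 0.00068) in the 28 libraries without it. Age itself stays among the open explanations, untested beside these.

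Chance could not be excluded for the counts of genes. Of 100 splits of the 34 libraries into bands of the same sizes, the real one included, 47 called as many genes as the real 120, and the highest other called 637. Among the other 99, the 28 splits that put younger replicate 8 in the middle band gave 0 splits with any call, whereas all 36 that put it in the older band called as many, which points to that library as the structure behind the calls. In the 33 libraries, 1532 genes between the bands had an unadjusted p under 0.05, and 6 of 100 splits gave as many (highest other 1983). For the slope on age there were 1202 such genes, and 19 of 100 orders of age gave as many (highest other 1936).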
